A study of Gossypium hirsutum with 4 samples.

How the data were processed

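Small RNA and degradome sequencing were done on hypocotyl and embryogenic callus of cotton, with 1 library of each kind per tissue and 4 libraries in all. Per the labels' protocols, small RNA was cut from a gel, ligated to adapters, amplified by PCR and sequenced. Per the same protocols, degradome libraries were made by ligating an adapter with an MmeI site to the 5′ phosphate of polyadenylated RNA, followed by MmeI digestion and further PCR. The deposited values are counts of reads, 1 line for each distinct sequence, with its length beside it, and are not normalised. The trimming tool, filters, aligner and genome build are not given in the sources used here, and the deposited files hold no alignments. Groups were taken from the tissue and sample type in the labels. The source name of both callus samples reads hypocotyls, against their tissue label of embryogenic calli. The tissue label was used, and every callus value rests on it.

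Reads of 18 to 24 nt were assigned to a family by ungapped alignment to 56 mature sequences of 40 families and 11 control sequences of 11 families. At most 1 mismatch and end shifts of 2 nt were allowed, with ties resolved by fewest mismatches, smallest shift and family name. The sequences were written from general knowledge before the data were examined, so they need not match the cotton forms. Assigned reads were divided by the total of clean reads and multiplied by 1000000 (reads per 1000000, RPM). The listed-family scale divides by the reads assigned to listed families instead. A family counted as higher or lower when it had 100 reads or more over both libraries, a ratio of 2-fold or more, and an exact conditional 95% interval for the ratio of 2 Poisson counts that excluded 1. A count of 0 was set to a floor of 3 reads per library, and the fold was then given as a bound. This bound is the ratio at the floor, and the exact 95% interval reaches smaller folds. A floor of 3 reads is 0.120 RPM in hypocotyl and 0.115 in callus. Shares have exact Clopper-Pearson intervals.

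Families given with values were the 10 with the most reads, the 10 with the largest rise and the 10 with the largest fall, and the controls, by a rule fixed before the data were examined. Only 8 families were above 0, so the second part holds 8. For unlisted sequences of 20 to 24 nt with 1000 reads or more the rule took 5 of each kind. It did not say how a count of 0 ranks. Both orders were looked at, the order with 0 at the floor was used, and the leader of the other is given too. Other members of the report were chosen after their values were seen, and are marked so or stand in list counts.

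Sequences of 5.8S rRNA, 3 tRNAs and a 551-nt part of 25S rRNA were written from general knowledge after the data had been seen, because no annotation of them was used here. Reads of 18 to 30 nt were matched to them exactly on both strands, and 549 positions of the 25S part were covered by sense reads in hypocotyl. Partner strands of miRNA duplexes were unassigned sequences of 20 to 22 nt that pair with a mature sequence with 2-nt 3′ overhangs. The first look at these partners used a score limit of 4.5 and 10 reads, and limits of 3.5 and 20 reads were taken later. All 4 combinations were run and are reported.

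For degradome tags, the planned search of transcripts for cleaved sites and the planned transcript lists were not run, since no transcript sequences were used here. The table of 99454 gene names that was at hand holds no sequences, so tags are reported by sequence. Tags that begin with the complement of miRNA positions 10 to 1 were counted in their place, against 100 shuffled sets of the same base composition. Words of 10 nt do not exist for positions 6 to 9, so words of 6 nt were used to compare these. The comparison with other offsets was added after the data were seen.

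The family calls were tested on simulated data drawn from the means of the 32 families and both library sizes. All simulated changes of 3-fold and 4-fold were called (100%), 0.744% of 1.5-fold changes were, and 95.3% of intervals held the true ratio. These simulations hold counting error only. Of 2000 simulated family members 100% were assigned to their family. These members were made within the limits of the assignment rule, so this checks the code and not how well the list covers cotton forms. Of 300 planted tags among 100300, the word search returned 303, with 3 by chance. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives covered the scaling, mismatches, end shift, read lengths, read minimum, what is counted, and the length of the complement.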

Results

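Small RNA and degradome libraries were made from cotton (Gossypium hirsutum, cultivar YZ1), to profile microRNAs (miRNAs) and the RNAs they cut during somatic embryogenesis, the formation of embryos from cultured somatic tissue. The 4 libraries fall into 4 groups of 1. Hypocotyls, the stems of seedlings below the seed leaves, came from seedlings of 7 days kept in the dark at 28 °C. Embryogenic callus, the cultured cell mass from which somatic embryos form, was taken 2 months after induction and kept in the light at 28 °C. Its explants had spent 40 days on medium with 1.0 mg/L indole-3-butyric acid and 0.1 mg/L kinetin. The tissues therefore also differed in light and hormone treatment. The small RNA libraries held 24948581 reads of 9773591 distinct sequences in hypocotyl and 25984975 reads of 12930499 distinct sequences in callus. The degradome libraries, which record the 5′ ends of uncapped polyadenylated RNA, held 15098505 tags in hypocotyl and 15519691 in callus. With 1 library per tissue there is no replicate check, and no difference between tissues was tested. Intervals are exact 95% intervals that cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

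The first comparison was the size of the small RNAs. Reads of 24 nt, the length typical of heterochromatic small interfering RNA, made up 42.9% of hypocotyl reads (Clopper-Pearson interval 42.93 to 42.97%) and 70.6% of callus reads (70.56 to 70.59%). Reads of 21 nt, the length of most miRNAs, made up 22.6% in hypocotyl (22.61 to 22.64%) and 7.28% in callus (7.27 to 7.29%). The 24-nt reads outnumbered the 21-nt reads 1.90 times in hypocotyl and 9.70 times in callus. Counted as distinct sequences the gap between tissues was narrower, at 8.07 times and 10.6 times. Among 24-nt reads, the share that began with A was 43.1% in hypocotyl and 58.5% in callus.

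**Figure D1:**
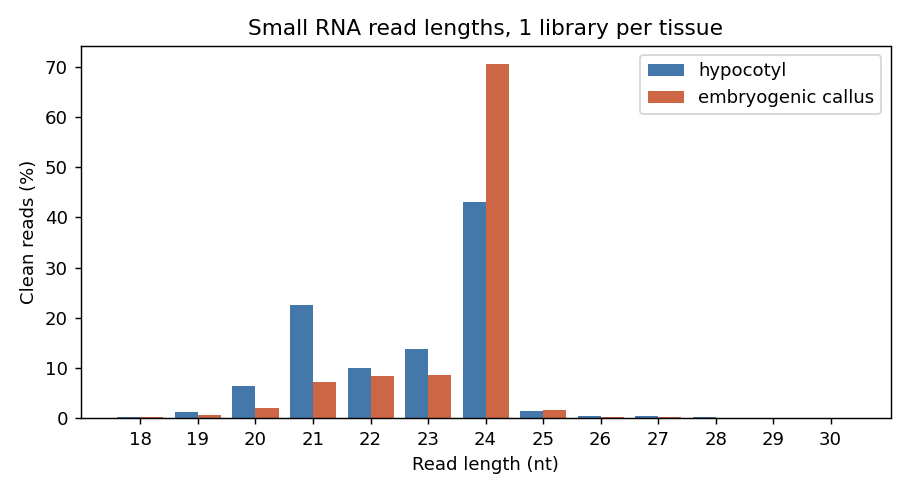
Percent of clean small RNA reads (vertical axis) at each read length in nt (horizontal axis), with 1 bar for the hypocotyl library and 1 for the callus library. The 24-nt bar stands at 42.9% in hypocotyl and 70.6% in callus, and the 21-nt bar at 22.6% and 7.28%.

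Reads of 40 listed families, 39 of them miRNAs and 1 the trans-acting siRNA from TAS3 that targets auxin response factors, took 14.7% of hypocotyl reads (14.71 to 14.73%) and 1.39% of callus reads (1.389 to 1.398%). These shares depend on the mismatch limit: with 2 mismatches they were 17.8% and 4.27%, with 0 mismatches 14.2% and 0.867%, and with the unlisted sequence TTGGACAGAGTAATCACGGTCG counted 17.7% and 4.23%. That sequence had 736364 callus reads, more than the 362098 callus reads of all listed families. The miR156/miR157 family, which targets SPL transcription factors of the juvenile to adult transition, held 85.5% of these reads in hypocotyl and 45.7% in callus. The 11 control families, which cotton should lack, had 30 reads in hypocotyl and 3 in callus together. Of the 32 families with 100 reads or more, 7 were at least 2-fold higher in callus in RPM (reads per 1000000 clean reads), 19 were at least 2-fold lower and 6 lay between. This split depended on the scaling. On the listed-family scale, which divides by the reads assigned to listed families, it was 17 higher and 7 lower. With median-of-ratios factors it was 13 higher and 11 lower. The listed-family total is mostly miR156/miR157 in hypocotyl, so the fall of this family raises the ratios of the others on that scale. Without this family the listed reads numbered 530876 in hypocotyl and 196789 in callus. The median family had a log2 ratio of callus over hypocotyl of -2.34 in RPM and of 1.06 on the listed-family scale. The direction was the same under 5 scalings for 8 families that were higher and 9 that were lower, and turned with the scaling for 15. Each scaling shifts all families by the same log2 amount, which against RPM was 3.40, 1.91, -0.016 and -0.185. For the 8 higher families, agreement over the scalings therefore adds little to the RPM ratio, since only the 2 small shifts lower it.

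The 8 families that were higher in callus under all 5 scalings included the miR390 and TAS3 pair, the copper-responsive families and families of phosphate nutrition. The TAS3 siRNA had 192 RPM in hypocotyl and 3402 in callus, a log2 ratio of 4.15 (4.11 to 4.19) and 6.49 relative to the median family. With 0 mismatches its log2 ratio was 2.72, from 1588 and 10865 reads. The miRNA that starts its production, miR390, had a log2 ratio of 2.41 (2.33 to 2.48), with 1685 and 9321 reads. The largest ratio among the 32 families was that of miR394, which targets an F-box gene of shoot meristem maintenance, at a log2 ratio of 6.13 (5.32 to 7.09) from 12 and 876 reads. With 0 mismatches it was 4.94 from 3 and 96 reads, under the minimum of 100 reads, so the call was lost. Both families of the copper list with enough reads were higher, miR408 at 4.82 (3.92 to 5.90) and miR397 at 2.28 (1.88 to 2.71; 2.90 with no end shift). The third, miR398, had 0 and 46 reads, which is at least 14.7-fold higher against a floor of 3 reads in the hypocotyl library. All 46 have 1 mismatch, and with 0 mismatches it had no reads. In the phosphate and sulphate list, miR399 had a log2 ratio of 4.38 (3.82 to 5.01) and miR827 of 2.25 (1.87 to 2.66). With 0 mismatches miR399 was at 1.79 from 18 and 65 reads and its call was lost in the same way. At a minimum of 1000 reads the calls of miR394, miR397, miR399, miR408 and miR827 were lost. miR403, which targets an ARGONAUTE gene, had 185 and 316 reads and a log2 ratio of 0.71 (0.45 to 0.98) in RPM, between the 2-fold limits, but 4.11 on the listed-family scale and 2.62 with median-of-ratios factors, where it counted as higher.

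The 9 families lower in callus under all 5 scalings included both phase change families. miR156/miR157 had 125915 RPM in hypocotyl and 6362 in callus, 19.8-fold lower (19.7 to 19.9) and -1.97 on the log2 scale relative to the median family. Its log2 ratio was -4.31, and -5.00 with no end shift. miR172, which targets AP2-like genes, was 14.8-fold lower (13.4 to 16.4). On the listed-family scale the log2 ratios of these families were -0.91 and -0.49, under the 2-fold limit, and both calls were lost. The other 7 of the 9 kept theirs there. Within miR156/miR157 the forms differed in size of change, as forms chosen after their values were seen. TTGACAGAAGATAGAGAGCAC had 1852236 and 7096 reads and was 272-fold lower in RPM, while TGACAGAAGAGAGTGAGCAC had 939481 and 83368 reads and was 11.7-fold lower. TTGACAGAAGAGAGTGAGCAC, 31.5% of the family's callus reads, was 3.52-fold lower (175845 and 51997 reads), and TGACAGAAGAGAGTGAGCACT was not lower, with 10221 and 10914 reads and a log2 ratio of 0.036. The cotton family miR2950 had 1182 and 3 reads, a ratio of 410-fold lower with a counting interval of 140 to 1993, and miR2948 was 24.6-fold lower (21.4 to 28.5). miR530 had 152 and 1 reads, 158.3-fold lower with an interval of 28.0 to 6294, and with 0 mismatches at least 52.4-fold lower from 151 and 0 reads. With no end shift it had 0 reads in both libraries and its call was lost. miR160, which targets auxin response factors, was 54.9-fold lower (21.1 to 203.5) from 211 and 4 reads, and miR319, which targets TCP genes, was 40.9-fold lower (15.7 to 151.9) from 6.29 and 0.154 RPM, and 25.3-fold lower with no end shift. No read of 2 nutrient families was found in callus, where miR2111 was at least 110-fold lower and miR395 at least 40.6-fold lower against a floor of 3 reads. At a minimum of 1000 reads the calls of miR160, miR319, miR395, miR530 and miR2111 were lost.

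For the abundant families in the middle of the range the direction turned with the scaling. miR165/miR166, which targets HD-ZIP III genes of organ polarity, had a log2 ratio of -2.87 (-2.88 to -2.85) in RPM and 0.54 on the listed-family scale. With 0 mismatches it was -4.56 in RPM. Of its full-length miR166 forms 0.218% ended in A in hypocotyl and 70.1% in callus. The values on these 2 scales were -3.31 and 0.086 for miR168, which targets AGO1, -2.64 and 0.76 for miR167, -2.46 and 0.95 for miR2949, and -2.33 and 1.07 for miR3476. miR535 was at -1.11 and 2.30, and turned with median-of-ratios factors as well, at 0.80. miR164, which targets NAC genes, lay between the 2-fold limits, with 11625 and 10941 reads and a log2 ratio of -0.15 (-0.18 to -0.11) in RPM. It turned too, to 3.25 on the listed-family scale and 1.76 with median-of-ratios factors, where it counted as higher.

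By list, in RPM and at the 2-fold limit, 2 of 5 auxin families were higher (miR390 and TAS3), 2 were lower (miR160, and miR167, which turned on the listed-family scale) and miR164, which turned there as well, lay between. Of 9 development families 1 was higher and 6 were lower, of 5 cotton families 5 were lower, and of 3 silencing pathway families 2 were lower. Of 4 phosphate and sulphate families 2 were higher and 2 lower, and both of the 2 copper families were higher. The NBS-LRR family miR482/miR2118 (1384 and 1230 reads) and miR3954, the 1 other eudicot family with enough reads, lay between. This rests on reads with 1 mismatch, since with 0 mismatches they had 52 and 8 reads and 1 and 2 reads, under the minimum of 100. Of the other eudicot list, miR479 had 16 and 0 reads and was not counted, but with 2 mismatches it had 7404 and 3 and counted as lower. The 2 MYB families, miR828 and miR858, had 46 reads in hypocotyl and 1 in callus together and were not counted, though with 2 mismatches miR858 had 120 and 79 and lay between. These counts move with the scaling as the totals do, since 12 of the 19 lower calls did not persist on the listed-family scale, and the 6 families between the limits counted as higher there and with median-of-ratios factors.

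**Figure D2:**
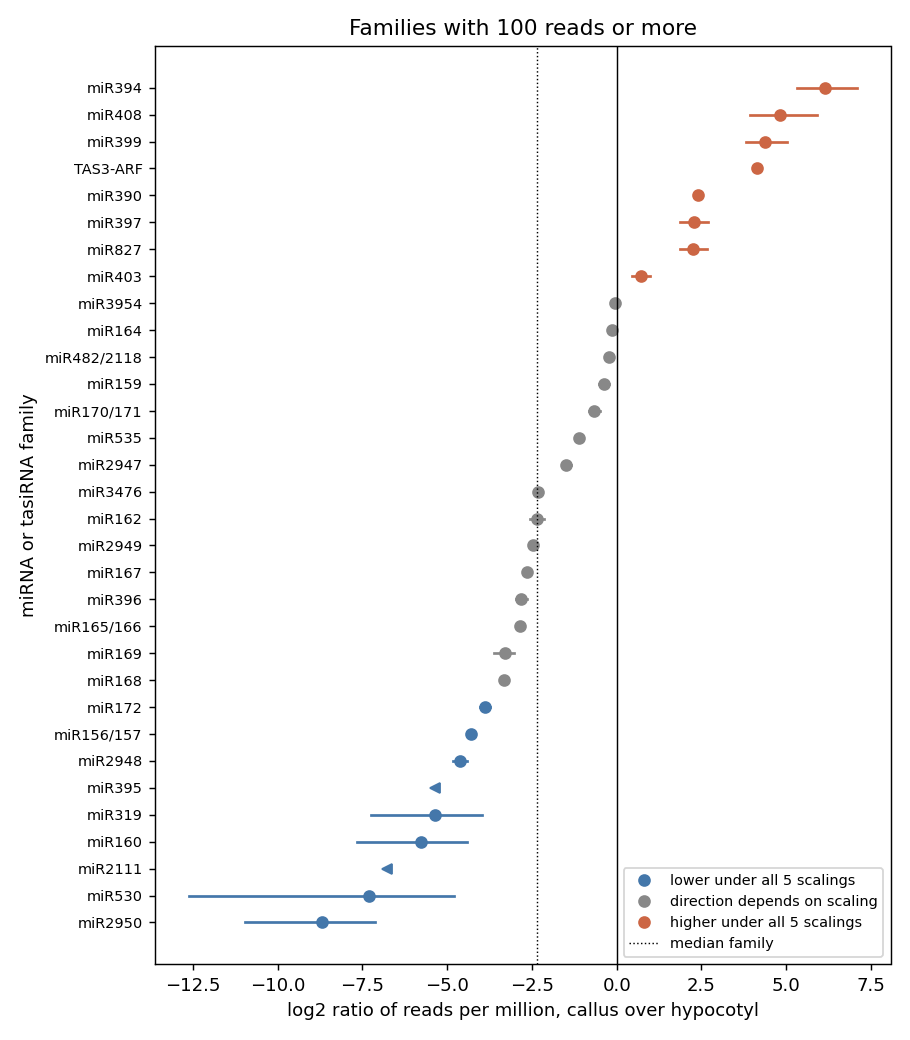
Log2 ratio of RPM in callus over hypocotyl (horizontal axis) for the 32 families with 100 reads or more (vertical axis), with lines for 95% counting intervals and left-pointing triangles for bounds from a callus count of 0. Colour marks the 8 families higher and 9 lower under all 5 scalings and the 15 whose direction depends on the scaling, and the dotted line marks the median family at -2.34.

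Outside the list, 1018 sequences of 20 to 24 nt had 1000 reads or more over both libraries, of which 317 were at least 2-fold higher in callus and 524 at least 2-fold lower in RPM. Of the 317, 179 were of 24 nt, and 55 matched the 25S rRNA part in sense and 27 in antisense. Of the 524, 354 were of 21 nt, 15 matched 5.8S rRNA, 5 tRNA-Ala and 2 the 25S part in antisense. The most abundant of the 1018, TTGGACAGAGTAATCACGGTCG, had 752283 reads in hypocotyl and 736364 in callus and was the most abundant sequence of the callus library. It differed from the listed miR3954 by A11T and A22G, counted from 1 at the 5′ end with the listed base first, and was left out of that family by the limit of 1 mismatch. The next were GGGGATGTAGCTCAGATGGT (78973 and 25020 reads) and GGGGATGTAGCTCAGATGGTA (46289 and 12005), both 5′ fragments of tRNA-Ala. TGGGACTCTATAAGAAGGTAA had 34465 and 6380 reads, and AACGACTCTCGGCAACGGATATCT, from 5.8S rRNA, had 34267 and 6558. The largest rises in RPM were in CTGTCGGCGCTTCTGCGGCTT (1 and 1353 reads), ATACTAACTGTACCTTGATCTCGT (2 and 1013), CTGAATCTTAGTGGATCGTGG (17 and 8563), TTGCATGGACAGTCGGTGCTT (7 and 1475) and TTCTGCGGCTTCGGCATGGAC (18 and 2722). The largest falls, with a 0 set to the floor of 3 reads, were in ACTCTCTTCCAAAGGCTTTGAG (4750 and 2 reads), CGTGATATTGGTTCGGCTCATC (7058 and 3), GCTCAAGAAAGCTGTGGGAGA (7469 and 4), TTTGCATGAACTAGGAGACGT (9564 and 6) and AGAGGCTGTAAAGGAGGCTAT (1566 and 1). In the other order, with a count of 0 ranked first, TCGGAAATACAAGAACCGGTA led with 3554 and 0 reads. It was 1234-fold lower at the floor of 3 reads and at least 1003-fold lower by the exact interval. In all, 10 sequences had no callus read.

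Fragments of the longer structural RNAs did not move together. Sense reads of 5.8S rRNA were lower in callus, at 9348 and 2280 RPM (0.244 of the hypocotyl level, 0.242 to 0.246), as were those of tRNA-Ala, at 9258 and 2642 RPM (0.285 of it, 0.283 to 0.288). Reads of a 551-nt part of 25S rRNA were higher in callus, with 2669 and 10565 sense RPM (3.96-fold, 3.93 to 3.99) and 925 and 4927 antisense RPM (5.33-fold, 5.25 to 5.40).

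The degradome was used to ask whether the listed RNAs cut their targets. Cutting opposite miRNA positions 10 and 11 leaves a 3′ fragment that begins with the complement of positions 10 to 1. In hypocotyl 3271 tags began this way, 3.74 times the mean of 100 sets of shuffled miRNAs (one-sided permutation p = 0.030), and in callus 2984 tags did, 3.62 times the mean (one-sided permutation p = 0.0099, the smallest that 100 sets can give). Each library had 62 distinct tags of this kind. The 10-nt words for positions 11 to 14 of the same miRNAs began 671 to 2242 tags in hypocotyl and 555 to 2266 in callus. Position 11 of miR157a gives the same word, TCTTCTGTCA, as position 10 of miR156a. Tags that begin with this word were therefore counted at both positions. Words of 6 nt, the longest that reach positions 6 to 9, did not set position 10 apart, with 240700 tags at position 10 and 235125 at position 7 in hypocotyl, and 261901 at position 10 and 311740 at position 9 in callus. Within 5′ ends of 18 nt and 2 or more tags, the 10-nt words stood at the first base in 36 hypocotyl ends, against a mean of 20.6 and a highest of 32 at the 8 following offsets, and in 44 callus ends, against 23.4 and 32. This background overlaps with the position-10 ends too. Ends that begin TCTTCTGTCAA carry the miR157a word CTTCTGTCAA at the first following offset.

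Of 63 such ends with 10 tags or more, 29 were at least 2-fold higher in callus, 28 at least 2-fold lower, and 11 were seen in both libraries. An end with 10 tags or more in 1 library and 0 in the other always passes 2-fold at the floor of 3 tags. Most of these calls therefore restate the low overlap of the 2 libraries. miR156/miR157 had the most, with 11 ends, 1064 hypocotyl tags and 1494 callus tags. Its end TCTTCTGTCAAATCAACC had 148 tags in hypocotyl and 1050 in callus, and TCTTCTGTCATCGCAACC had 323 and 194. miR160 had 626 tags in hypocotyl and 67 in callus, led by GAGCCAGGCATGAACCGT with 376 and 0. The single miR164 end, TGCTTCTCCAATCCCGTC, had 437 and 0 tags, the single miR394 end, AGAATGCCAAACATATGG, had 0 and 327, and the single miR530 end, TGCAAATGCAACTTCGAG, had 211 and 0. TAS3 ends had 119 and 347 tags. Not all of these families had more ends than at other offsets. For ends of 2 tags or more, summed over both libraries, the number at the first base and the mean at the 8 following offsets were 17 and 4.125 for miR156/miR157, 7 and 0.5 for miR160, 7 and 4.125 for TAS3, 4 and 1.5 for miR394, 1 and 1.375 for miR164, and 1 and 1.5 for miR530. The number of miR164 and miR530 ends is thus no higher than at the other offsets. This count ignores how many tags an end had, and tags at the other offsets were not counted. It therefore cannot tell whether these single ends are background. No transcript was named, because no transcript sequences were used here. The commonest count above 4 was 27 reads per distinct tag in hypocotyl and 26 in callus, and 6.91% of all ends with 10 tags or more were seen in both libraries. How many molecules lie behind a tag was not measured, and no counting interval is given for tags.

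**Figure D3:**
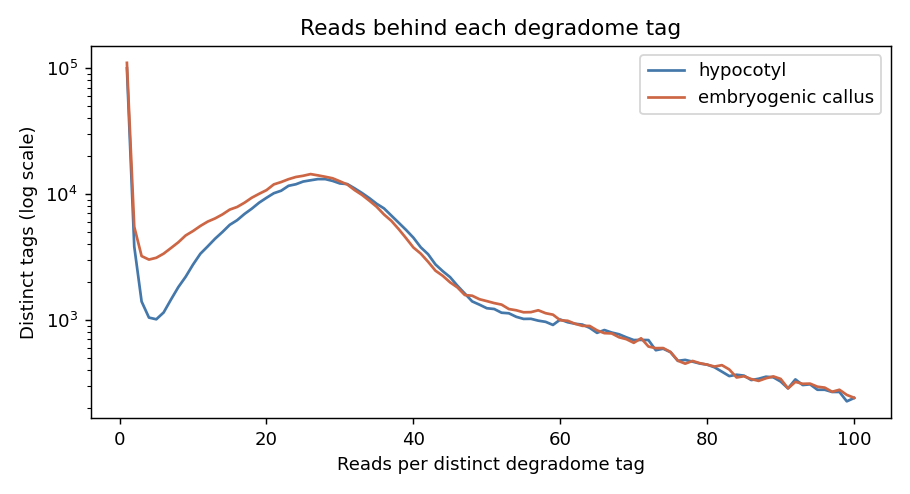
Number of distinct degradome tags (vertical log axis) by the reads that each tag had (horizontal axis, 1 to 100), with a line for each library. Both lines have a peak at 1 read and another at 27 reads in hypocotyl and 26 in callus.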

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

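All tests below were chosen after the results were seen, except the one on the median family. Families that cotton should lack had reads in the hypocotyl small RNA library above the 3 reads that a count of 0 allows: the Brassicaceae family miR158 had 13, the animal family miR-122 had 10 and the animal family let-7 had 4. Of these hypocotyl reads, 11 of miR158, 0 of miR-122 and 1 of let-7 matched with 0 mismatches. In the callus library these families had 0, 0 and 2 reads. Degradome tags of 31 nt or longer, beyond the reach of MmeI, made up 1.89% of callus tags and 0.0982% of hypocotyl tags.

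Most listed families were lower in callus in RPM, by a median log2 ratio of -2.34. The larger 24-nt share alone would lower every family by the same log2 shift of -0.96. The counting intervals of 32 of 32 families exclude that shift, 13 above it and 19 below, but these intervals hold counting error only, and without replicate libraries this decides nothing. Dilution stays open, also for the median family: with 24-nt reads left out of the total its log2 ratio was -1.39, with a bootstrap interval over families of -2.35 to 0.70 that includes 0. Tissue, light and hormones differ together between these 2 libraries, and their effects were not tested.

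In hypocotyl 0.218% and in callus 70.1% of the full-length miR166 forms ended in A, as TCGGACCAGGCTTCATTCCCA (687 and 35752 reads) rather than TCGGACCAGGCTTCATTCCCC (292780 and 13466). A library-wide addition or misreading of a last A is argued against by the 17 forms of other families whose hypocotyl reads mostly do not end in A, whose share of A changed by a median of 0.0034 points with an upper quartile of 0.267. With these forms chosen by the listed last base, as at first, the values were 0.0136 and 0.276. The exception among the 17 was miR169, which rose by 96.7 points on 244 and 83 reads. Outside them, miR165a, of the same family as miR166, went from 0.279% to 53.8% on 358 and 52 reads, and miR167a, which mostly ended in A already, from 69.0% to 92.8%. Reads of another family member whose gene ends in A may account for it, but 70.1% cannot be set against a gene sequence here, so this cannot be told apart from a tissue-specific change of the end.

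Antisense reads on the 25S rRNA part were 25.7% of its reads in hypocotyl and 31.8% in callus (31.7 to 31.9%). Strand exchange during library preparation is argued against, since the antisense share of 5.8S rRNA in callus was 1.48% and that of tRNA-Ala 0.00146%. Breakdown of the rRNA yields sense fragments, and with strand exchange at the rate of 5.8S rRNA it would give up to 0.290% antisense reads in hypocotyl and 1.58% in callus, the upper bounds for 5.8S. As the source of the antisense reads it is argued against, on that premise, by the lower bounds of their share, 25.5% and 31.7%. The premise was not tested, and this share is the pattern that raised the question. The comparison is therefore no separate test beyond that of strand exchange. For the sense reads breakdown stays open. Small interfering RNA made from rRNA may be the source of the antisense reads, as a hypothesis that 31.8% alone does not test, and the difference between tissues stays open with light and hormones.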

How the results depend on the processing

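Alternatives that leave out rRNA and tRNA reads, count the abundant unlisted sequence as miR3954, or use other offsets as background were chosen after seeing the data. The causes of the changes below were not tested. As distinct sequences the 24-nt share was 58.1% in hypocotyl and 71.0% in callus and the 21-nt share 7.19% and 6.67%, so the 21-nt gap between tissues nearly closed. Without sequences seen once these shares were 37.1% and 72.3%, and 29.5% and 7.26%. Without rRNA and tRNA reads they were 43.6% and 71.7%, and 22.7% and 7.03%. The miRNA share in hypocotyl and callus was 14.2% and 0.867% with 0 mismatches, 17.8% and 4.27% with 2, 13.3% and 1.06% with no end shift, 15.4% and 1.44% of reads of 20 to 24 nt, and 17.7% and 4.23% with the unlisted sequence. Families at least 2-fold higher numbered 17 and lower 7 on the listed-family scale, 13 and 11 with median-of-ratios factors, and 2 and 14 with a minimum of 1000 reads, against 7 and 19. The main and the listed-family scale shared 7 higher and 7 lower calls. On the listed-family scale 7 of 24 named families turned direction: miR165/miR166 (0.54), miR167 (0.76), miR168 (0.086), miR2949 (0.95), miR3476 (1.07), miR535 (2.30) and miR164 (3.25), and of these miR535 (0.80) and miR164 (1.76) also with median-of-ratios factors. The listed-family total leaves out the abundant unlisted sequence and is mostly miR156/miR157 in hypocotyl. With the unlisted sequence counted, the shares of 17.7% and 4.23% would set a smaller shift, and these values would be lower. At those shares only miR535 and miR164 of the 7 would still turn. This follows from the shares and was not run as a setting. No named family turned under the other 6 settings, but with no end shift 23 of the 24 could be compared, as miR530 had no reads there. The excess of position-10 tags kept its side of the threshold with distinct tags and with 9 nt. With distinct tags it was 2.42 times the shuffled mean in hypocotyl and 2.18 in callus. The comparison with other offsets counts ends of 2 tags or more, so both unit and background differ. Such ends stood at 1.75 times the mean of other offsets in hypocotyl and 1.88 in callus. Both had an exact one-sided p of 0.111, the smallest that 9 offsets can give. With a minimum of 30 tags, 14 ends were at least 2-fold higher and 19 lower. The alternatives for cleaved sites, for tags scaled to those matched to transcripts and for transcript lists were not run, for want of transcript sequences. No paired analysis was possible because each group has 1 library. Families of few reads are limited by depth, as the interval of 28.0 to 6294 for miR530 shows.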

Other observations

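The tests in this part were chosen after the results were seen. The partner strands of miRNA duplexes, which are cut from the same precursor, were counted at 4 settings. They gave 20 reads or more for 14 families at the strictest, a score limit of 3.5, and for 23 at a limit of 4.5. With 10 reads or more it was 17 and 25 families. The partner of miR160, GCGTATGAGGAGCCATGCATG, had 10313 reads in hypocotyl and 31 in callus, and all miR160 partners together had 53.1 times the mature reads in hypocotyl. The leading miR396 partner, GCTCAAGAAAGCTGTGGGAGA, had 7469 and 4 reads and the leading miR172 partner 1224 and 2. Of the 8 families higher in callus under all 5 scalings, 3 had partners at the stricter limits given below, and these had more callus reads, with 11 and 259 for miR408, 43 and 128 for miR827 and 29 and 246 for the leading miR390 partner. In the most abundant TAS3 form, TTCTTGACCTTGTAAGACCCA, reads went from 3024 to 75095.

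A hypothesis is that the family differences arise at the precursor, so that both strands change together, which may hold for part of the families. At a score limit of 3.5 and 20 partner reads, both strands had the same direction in RPM in 14 of 14 families, but a change of scale shared by all reads gives that too. Relative to the median family, both strands lay on the same side in 11 of 14. The looser limits used at first gave less: at 4.5 and 20 reads 19 of 23 families had the same direction and 16 the same side, and at 4.5 and 10 reads 21 of 25 and 17. In that setting the partners of 3 of 6 higher families were higher. At 3.5 and 10 reads it was 17 of 17 and 12. Shuffled sequences gave a mean of 4.22 partners at 3.5, against 85 for listed ones, and 38.0 against 123 at 4.5. The result therefore depends on the limit, and the hypothesis stays open. Families are not independent replicates.

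Among 21-nt sequences with 100 reads or more, 86.6% of those in hypocotyl were also seen in callus and 99.03% of those in callus were seen in hypocotyl. At 10 reads or more these shares were 60.6% and 84.2%, and over all 21-nt sequences 11.2% and 9.09%. Antisense reads of the 25S rRNA part were 48.2% of 21 nt and 19.9% of 22 nt in hypocotyl, and 23.6% and 41.0% in callus.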
